A study of Homo sapiens with 12 samples.

How the data were processed

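RNA of 12 samples of the RWPE-1 prostate epithelial line was analysed, 4 each of empty vector cells without U0126, Flag-ERG cells with U0126 and Flag-ETV1 cells with U0126. Per the labels, total RNA was primed with oligo-dT, copied to double-stranded cDNA and labelled for 2-colour NimbleGen arrays. The test sample carried Cy3 on every array and RNA of U0126-treated empty vector cells carried Cy5, so no array has swapped dyes. The deposited values are 1 log2 ratio per probe and array, for 135096 probes. Base 2 is taken as the maker's usual base and is not stated, and the numerator, the background correction and the normalization within an array are not given in the sources used here. The array medians lie between -0.0087 and 0.0115, so each array appears centred near 0. The planned basis for the direction of the ratio, higher ERG and ETV1 on the arrays of their own construct, did not settle it. It is taken as test over reference because known MAPK targets stood above 0 on the arrays without U0126 and because 3 unnamed accessions stood above 0 by over 5 on the arrays of 1 construct alone, a basis chosen after the values were seen. The accessions bear on the direction only if they belong to sequences that the constructs carry, which was not tested.

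Single-channel intensities were not used here, so signal over background and saturation could not be checked, and no filter on dim probes could be made. Probes are identified by accession, with 3 probes for 45031 of 45033 accessions. Names came from a RefSeq gene table of the human assembly GRCh38.p14, matched on accession without its version and used for names only; no coordinates are given, since no build is named for the array. It named 18865 of 20952 curated mRNA accessions, 1 of 6043 predicted mRNA accessions and none of the 18038 others, in all 18866 accessions, 56598 probes and 17185 genes. The 26167 accessions without a name were left out of the comparisons and are summarised in the closing section. A gene's value on an array was the median over its probes, and 1349 genes had more than 3. Probes of 1 gene disagreed (means beyond 1.5-fold in both directions) in 91 genes in the untreated comparison, 76 with ERG, 62 with ETV1 and 12 between ERG and ETV1. Genes with near-identical copies, such as paralogs, may share signal, and probe sequences were not used to test this.

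Log2 ratios were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in 1 fit of all 12 arrays with 3 group means and a shared spread. Each group mean was tested against 0, and the ERG mean against the ETV1 mean. The reference is the control RNA itself and no control sample was hybridised against it, so a ratio against 0 leaves out the control's own spread. A gene was called when its Benjamini-Hochberg adjusted p over 17185 genes was under 0.05 and its mean changed by at least 1.5-fold. The median residual SD was 0.196 and the prior had 14 degrees of freedom. No 2 arrays of a group were near-duplicates: the SD of their difference over genes was 0.277 to 0.332. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

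There were 19 gene lists from textbook knowledge, holding 423 entries of which 414 were measured. They covered MAPK feedback and ETS output, immediate early genes, growth factors and cytokines, proteolysis with adhesion and migration, mesenchymal genes, epithelial junction genes, prostate basal and luminal markers, keratinocyte differentiation, cell cycle and mitosis, ribosome biogenesis and MYC targets, FOXO and quiescence, cholesterol synthesis, unfolded protein and amino acid stress, the interferon response, and markers of endothelial, fibroblast and smooth muscle, blood and neuroendocrine cells. Each list was tested with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over 19 lists within a comparison). Camera tests a net shift against other genes, so rises and falls within a list can offset each other. Alternatives were camera with an estimated correlation, fry's directional test of whether a list moves on balance 1 way, and fry's mixed test of change in either direction. ERG was left out of the endothelial list where ERG arrays were tested.

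The rule for genes named in the text took, per comparison, the 12 largest rises and 12 largest falls among called genes with the same sign on every array (no overlap between groups for ERG against ETV1), up to 4 called members per list with the largest change, and the 8 leading genes per direction shared by a pair of comparisons. ERG and ETV1 were named first, and a named gene's value is also given in other groups. Some genes that the rule took are not reported here. List members without a call are given with their values. Called list members named outside the rule were chosen after their values were seen: ATF3, DSC2, ETV4, ETV5, FOS and TXNIP without U0126, ATF3, S100A9 and VIM with ERG, many members of the MAPK, mesenchymal, epithelial junction, immediate early and keratinocyte lists with ETV1, and IL11, SLC4A7 and SPRY4 between ERG and ETV1. The comparisons, lists, naming rule and most alternatives were fixed before the data were examined.

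Overlaps between comparisons were counted per direction and set against the product of list lengths over genes tested. They were also set against 100 simulated draws of unchanged groups with a reference shared by arrays of the same replicate number. The share of the variance given to this reference was set to 14.6%. Overlaps were also recomputed from sets of 2 arrays per group with different replicate numbers. All 3 groups carry the replicate numbers 1 to 4. After group means were removed, ERG and ETV1 arrays of the same number correlated across genes at 0.297, 0.123, 0.205 and 0.282. The data thus hint that the numbers pair these 2 groups, which the labels do not say. ERG replicate 2 correlated as well with ETV1 replicate 1 (0.131). Within these groups, replicates 1 and 2 correlated at -0.163 (ERG) and -0.152 (ETV1), and 3 and 4 at -0.221 and -0.219. Removing the mean of 4 arrays makes correlations within a group negative on average, so the less negative pairs are the more alike. Other replicates of a group correlated at -0.321 or lower, so pairing number by number is not established. The comparison without the block stayed the stated one, and values with the replicate block are given where they change a call. Other alternatives were median centring, scaling to one median absolute deviation, quantile normalization, mean over probes, single probes, leaving out genes with disagreeing probes or the more variable ones, fitting only the arrays compared, robust eBayes, a random replicate block, other thresholds and each array left out in turn.

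The procedure was tested on simulated data with 200 of 17185 genes changed. In the ERG comparison it called 58.2% of 1.5-fold changes and 100% of 2-fold and 4-fold changes, with 2 of 16985 unchanged genes called. Between ERG and ETV1 it called 41.8%, 97% and 100%, with 4 of 16985 unchanged genes called, and 0 of 17185 in an unchanged untreated group. Camera found the 1 shifted list (adjusted p = 4.3e-58) and 0 of 18 others. The simulated noise was independent between genes and arrays, with no shared reference or dye term. The low numbers of false calls may therefore not hold for the real arrays. Simulated changes of 1.5-fold lie on the threshold itself, so part of them is missed by construction. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9.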

Results

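Gene expression was measured in RWPE-1 cells, an immortalized line of human prostate epithelium kept in serum-free keratinocyte medium with epidermal growth factor and pituitary extract. The cells carried a retroviral construct that was empty or expressed Flag-tagged ERG or Flag-tagged ETV1, transcription factors of the ETS family whose genes are rearranged and overexpressed in many prostate cancers. U0126 inhibits MEK, the kinase that activates the ERK MAP kinases, and was given at 10 µM for 6 h before the RNA was collected. On each of 12 NimbleGen expression arrays, Cy3-labelled RNA of a test sample was hybridised together with Cy5-labelled RNA of empty vector cells that had received U0126. The test samples were empty vector cells without U0126, Flag-ERG cells with U0126 and Flag-ETV1 cells with U0126, with 4 arrays in each of the 3 groups. The design text of the series counts 16 samples in 4 conditions, a number that is reached when the reference RNA is counted as a condition, and 12 arrays were analysed here. The series title sets the question: whether oncogenic ETS proteins control a Ras/MAPK expression program when MAPK signalling is blocked.

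The arrays measured 17185 genes with a name in the table used here, from 135096 probes. The correlation of log2 ratios across genes was 0.571 to 0.775 between arrays of one group and 0.143 to 0.342 between arrays of different groups, where genes are not independent replicates. The median standard error was 0.098 for a group mean and 0.139 for a difference between groups, and the number of arrays limits the precision. Values below are mean log2 ratios to U0126-treated vector cells ± SD over 4 arrays (n = 4 in each group) and are called higher or lower by limma (adjusted p under 0.05 and at least 1.5-fold). The labels name the dyes but not the numerator of the ratio, so the direction, test over reference, is likely rather than stated. It rests on values seen in the data: DUSP6 and SPRY4, known targets of MAPK signalling, stood far above 0 on the arrays without U0126.

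The probes named for ERG and ETV1 did not stand out on the arrays of their own construct. ERG read -0.02 ± 0.39 in vector cells without U0126, 0.26 ± 0.09 in Flag-ERG cells and 0.23 ± 0.32 in Flag-ETV1 cells. ETV1 read 0.60 ± 0.24, 0.12 ± 0.13 and 0.10 ± 0.14 in the same order, and its value without U0126 was called higher (adjusted p = 2.48e-05). That call is lost without untreated replicate 3 (0.58) and without untreated replicate 4 (0.49). Where these probes lie relative to the cloned sequences is not known, so they check nothing about the labels. Some probes without a gene name read 6.35 ± 0.19 with ERG, against 0.07 ± 0.28 with ETV1. Others read 5.48 ± 0.39 and 5.07 ± 0.34 with ETV1, against -0.09 ± 0.36 and -0.14 ± 0.24 with ERG. Whether the constructs carry their sequences was not tested.

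In vector cells, the absence of U0126 went with much higher RNA of the feedback regulators of MAPK signalling. DUSP6, a phosphatase that inactivates ERK, reached 4.45 ± 0.28, a 21.8-fold difference, and SPRY4, an inhibitor of receptor tyrosine kinase signalling, reached 3.85 ± 0.17. The direction of the ratio was itself taken from these targets, so the sign of their values and of the MAPK list below is no independent finding. DUSP4, another ERK phosphatase, stood at 3.80 ± 0.14, FOSL1, an AP-1 subunit, at 3.47 ± 0.04, and PHLDA1 at 3.30 ± 0.20. At the other end, the xenobiotic-metabolising cytochromes CYP1A1 and CYP1B1 stood at -3.41 ± 0.22 and -3.25 ± 0.10, and BMF, a pro-apoptotic BH3-only protein, at -2.92 ± 0.26. In all, 670 genes were higher and 748 lower than with U0126, 1418 of 17185 tested, and 310 differed by at least 2-fold, 184 of them higher and the others lower.

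Of the 25 measured genes of MAPK feedback and ETS output, 22 rose without U0126, none fell and 3 were not called (camera in limma, adjusted p = 3.25e-27, and 1.14e-05 with an estimated correlation). Beside those named above they included the receptor EPHA2 (2.58 ± 0.16), the phosphatase DUSP5 (2.36 ± 0.12), and ETV5 (1.67 ± 0.13) and ETV4 (0.59 ± 0.14), ETS factors that MAPK signalling induces. The 3 without a call were EPHA4 (-0.57 ± 0.18), IL11 (-0.11 ± 0.13) and HMGA1 (0.10 ± 0.23). Counts adjusted over the list alone were identical to those over all genes, in this list and in every list below.

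**Figure D1:**
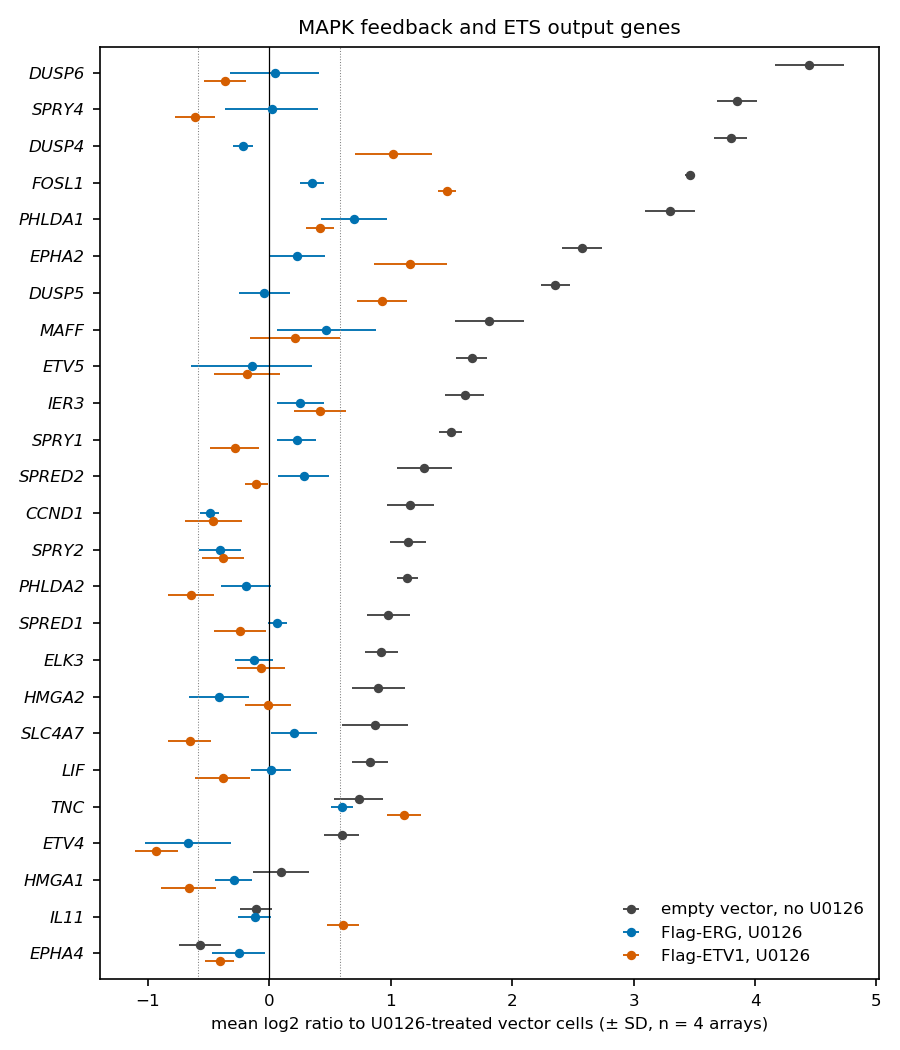
Mean log2 ratio to U0126-treated vector cells (x axis) of the 25 measured genes of MAPK feedback and ETS output, with points for the 3 groups, bars of 1 SD over 4 arrays and dotted lines at 1.5-fold. Without U0126, 22 of the genes were called higher, against 2 with ERG and 6 with ETV1.

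Genes that growth signals induce within minutes split. Of 25 immediate early genes, 9 rose and 3 fell (adjusted p = 0.000929, and adjusted p = 0.0215 with an estimated correlation). MYC (2.36 ± 0.14), the survival factor MCL1 (1.51 ± 0.21) and FOS (1.29 ± 0.22) rose, while KLF2 (-2.01 ± 0.19), the antiproliferative BTG2 (-1.37 ± 0.22) and ATF3 (-0.95 ± 0.26) fell. Among ribosome biogenesis genes and MYC targets, 16 of 26 rose and none fell (adjusted p = 6.88e-14, and 0.00139 with an estimated correlation), with the ribosome assembly factors RRS1 at 1.34 ± 0.16, NOP16 at 1.31 ± 0.16 and PPAN at 1.19 ± 0.24.

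Secreted signals and the machinery of adhesion moved in the same direction. Of 26 growth factors and cytokines, 12 rose and none fell (adjusted p = 1.66e-11, and 0.00025 with an estimated correlation), including the lymphatic growth factor VEGFC (2.03 ± 0.13) and the EGF receptor ligands TGFA (1.41 ± 0.06) and HBEGF (1.29 ± 0.30). Of 36 genes of proteolysis, adhesion and migration, 12 rose and none fell (adjusted p = 3.52e-07, and 0.000944 with an estimated correlation), led by the collagen-binding integrin ITGA2 (2.67 ± 0.37), ITGB6 (1.45 ± 0.31) and the metalloproteinase MMP3 (1.43 ± 0.24).

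Other lists were lower without the inhibitor. Of 24 FOXO and quiescence genes, 7 fell and 1, TXNIP (0.65 ± 0.51), rose (adjusted p = 1.56e-06, and 0.00139 with an estimated correlation). Beside BMF, the fallen members included TP53INP1 (-1.15 ± 0.07) and PIK3IP1 (-1.09 ± 0.37), an inhibitor of PI3 kinase. Of 28 epithelial junction genes, 5 fell and none rose (adjusted p = 0.000893, and 0.021 with an estimated correlation), in the epithelial transcription factors ELF3 (-2.49 ± 0.05), OVOL1 (-1.46 ± 0.09) and GRHL3 (-1.36 ± 0.15) and the junction proteins CGN (-0.82 ± 0.08) and DSC2 (-0.60 ± 0.10). In the list of unfolded protein and amino acid stress, 4 of 20 genes fell and none rose, with CHAC1, a glutathione-degrading enzyme induced by ATF4, at -2.01 ± 0.13 and the cystine transporter SLC7A11 at -0.96 ± 0.22 (adjusted p = 0.0095, and adjusted p = 0.0598 with an estimated correlation).

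The call of 2 further lists did not hold with an estimated correlation. Of 21 cholesterol synthesis genes 2 fell, STARD4 (-0.74 ± 0.10) and MVK (-0.60 ± 0.16) (adjusted p = 0.043, and adjusted p = 0.0719 with an estimated correlation). The list was also lost with the replicate block (adjusted p = 0.0504) and without untreated replicate 3 (adjusted p = 0.093). Of 22 interferon response genes 2 fell, IFIT2 (-0.76 ± 0.39) and IFIT3 (-0.73 ± 0.20) (adjusted p = 0.000929, and adjusted p = 0.175 with an estimated correlation). Mesenchymal genes (3 of 19 rose, 2 fell, adjusted p = 0.421) and keratinocyte differentiation genes (4 of 26 fell, 0.0765) did not pass the list test. Neither did basal cell markers (3 of 14 fell, 0.612), luminal cell markers (1 of 18 rose, 1 fell, 0.612) or cell cycle genes (2 of 36 fell, 0.281). Calls close to 1.5-fold were lost without 1 array for DSC2 (-0.56 without untreated replicate 1), ETV4 (0.58 without replicate 2 and 0.53 without replicate 4), MVK (-0.52 without replicate 3) and TXNIP (0.49 without replicate 3 and 0.52 without replicate 4). Here and with ERG or ETV1 the ratio is set against 0, which leaves out the spread of the control RNA and, with no dye swap, cannot remove a gene-specific dye effect.

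Flag-ERG cells were compared with vector cells with U0126 present in both. RSAD2, the antiviral protein viperin, reached 2.09 ± 0.13, CXCL11, an interferon-induced chemokine, 1.99 ± 0.19, and OAS1, which senses viral double-stranded RNA, 1.55 ± 0.15. Apolipoprotein D (APOD) reached 1.63 ± 0.17 and the ligand IGFL1 1.68 ± 0.25. The amino acid transporter SLC38A5 stood at -3.65 ± 0.21, a 12.5-fold difference, the extracellular matrix protein SPARC at -2.48 ± 0.11, the squamous keratin KRT13 at -2.29 ± 0.26 and tissue factor, F3, at -2.24 ± 0.13. The comparison called 310 genes higher and 431 lower, 741 in all, of which 35 and 111 differed by at least 2-fold.

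The list of MAPK feedback and ETS output did not pass its test with ERG. Of its 25 genes, PHLDA1 (0.69 ± 0.27) and the matrix protein TNC (0.60 ± 0.09) rose, ETV4 (-0.67 ± 0.35) fell and 22 were not called (adjusted p = 0.826). DUSP6 stood at 0.05 ± 0.37 and SPRY4 at 0.02 ± 0.38. Among immediate early genes 1 rose, ATF3 (0.63 ± 0.21), and 4 of 25 fell, among them EGR1 (-1.40 ± 0.28), the matricellular protein CCN1 (-1.06 ± 0.13) and FOS (-0.75 ± 0.33), and the list did not pass (adjusted p = 0.822). None of the 26 growth factors and cytokines rose and 7 fell, the EGF receptor ligands AREG (-1.50 ± 0.26) and EREG (-0.88 ± 0.08) and the activin subunit INHBA (-1.10 ± 0.14) among them (adjusted p = 0.0771). Of 36 genes of proteolysis, adhesion and migration, the integrins ITGB6 (1.25 ± 0.29) and ITGA2 (1.10 ± 0.25) and the actin bundler FSCN1 (0.71 ± 0.28) rose and the gelatinase MMP2 (-0.68 ± 0.20) fell (adjusted p = 0.177).

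Of 22 interferon response genes, 13 rose with ERG and 1 fell (adjusted p = 8.44e-12, and adjusted p = 0.0741 with an estimated correlation). The risen members included IFI6 (1.58 ± 0.33), OASL (1.47 ± 0.38) and the ubiquitin-like modifier ISG15 (1.38 ± 0.30), and the fallen one was BST2 (-2.44 ± 0.15), which tethers budding virions. Of 26 keratinocyte differentiation genes, 8 fell, including the cornified envelope precursors SPRR1A (-1.67 ± 0.10) and SPRR3 (-1.40 ± 0.22) and the cross-linking enzyme TGM1 (-1.12 ± 0.14), and S100A9 (0.69 ± 0.14) rose (adjusted p = 0.00356, and adjusted p = 0.118 with an estimated correlation). Of 19 mesenchymal genes, 6 fell, including SPARC, the fibroblast surface protein THY1 (-1.11 ± 0.12) and the cadherins CDH2 (-1.05 ± 0.21) and CDH11 (-1.03 ± 0.23), and vimentin (VIM, 0.66 ± 0.05) rose (adjusted p = 0.0266, and adjusted p = 0.118 with an estimated correlation).

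Shifts with few called members were seen in 3 lists of metabolism and stress. Cholesterol synthesis had 2 of 21 genes higher, the sterol sensor INSIG1 (0.81 ± 0.25) and the demethylase CYP51A1 (0.61 ± 0.12), and none lower (adjusted p = 0.0266, and adjusted p = 0.0921 with an estimated correlation). In the stress list, XBP1 (0.62 ± 0.18), a transcription factor of the unfolded protein response, was the 1 gene of 20 that rose (adjusted p = 0.0166, and adjusted p = 0.0921 with an estimated correlation). The 24 FOXO and quiescence genes held no call, with a median of -0.17 (adjusted p = 0.0266, and adjusted p = 0.0921 with an estimated correlation). Without ERG replicate 4 the FOXO list (adjusted p = 0.076) and the cholesterol list (0.0535) no longer passed. Epithelial junction genes (2 of 28 rose, DSP and CLDN1, adjusted p = 0.198), ribosome and MYC genes (0 of 26 called, 0.826) and cell cycle genes (0 of 36 called, 0.36) did not pass. Basal markers (1 of 14 rose, 2 fell, 0.977) and luminal markers (1 of 18 rose, 1 fell, 0.826) did not pass either. For the basal markers the median was 0.08 and the mean -0.04, and for the luminal markers -0.03 and 0.02. Calls close to 1.5-fold were lost for TNC (0.57), ETV4 (-0.52) and XBP1 (0.56) without ERG replicate 1, for MMP2 (-0.58) and XBP1 (0.58) without replicate 2, for CYP51A1 (0.58) without replicate 3, and for CYP51A1 (0.57) and ATF3 (0.56) without replicate 4.

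Flag-ETV1 cells were compared with vector cells in the same way. The receptor tyrosine kinase ROS1 reached 3.28 ± 0.25, the methyltransferase NNMT 2.98 ± 0.31, N-cadherin (CDH2) 2.51 ± 0.15 and SPARC 2.46 ± 0.22. GSDMC, a gasdermin, stood at -3.86 ± 0.17, a 14.5-fold difference, the metalloreductase-like STEAP1 at -3.33 ± 0.07, the serine proteases KLK5 and KLK6 at -3.27 ± 0.15 and -2.83 ± 0.17, and the gap junction protein GJB2 at -2.16 ± 0.33. There were 625 genes higher and 975 lower, 1600 in all, and 155 and 286 differed by at least 2-fold.

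Of 19 mesenchymal genes, 11 rose with ETV1 and 2 fell (adjusted p = 1.6e-06, and 0.0191 with an estimated correlation). Beside CDH2 and SPARC, vimentin (1.77 ± 0.24), the collagen cross-linking enzyme LOX (1.64 ± 0.19) and the transcriptional repressor ZEB1 (1.60 ± 0.09) rose, while THY1 (-1.18 ± 0.27) and COL5A1 (-0.61 ± 0.22) fell. Of 28 epithelial junction genes, 12 fell and 6 rose (adjusted p = 0.00131, and 0.0301 with an estimated correlation). The fallen members included the trafficking GTPase RAB25 (-1.74 ± 0.16), OVOL1 (-1.61 ± 0.14), the tight junction claudin CLDN7 (-1.40 ± 0.23), EPCAM (-1.28 ± 0.09) and E-cadherin (CDH1, -0.65 ± 0.05). The risen members were the desmosomal genes DSP (0.94 ± 0.31), DSG3 (0.81 ± 0.17), DSC3 (0.80 ± 0.24) and PKP1 (0.77 ± 0.29) and the tight junction genes CLDN1 (0.73 ± 0.30) and TJP1 (0.62 ± 0.16).

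**Figure D2:**
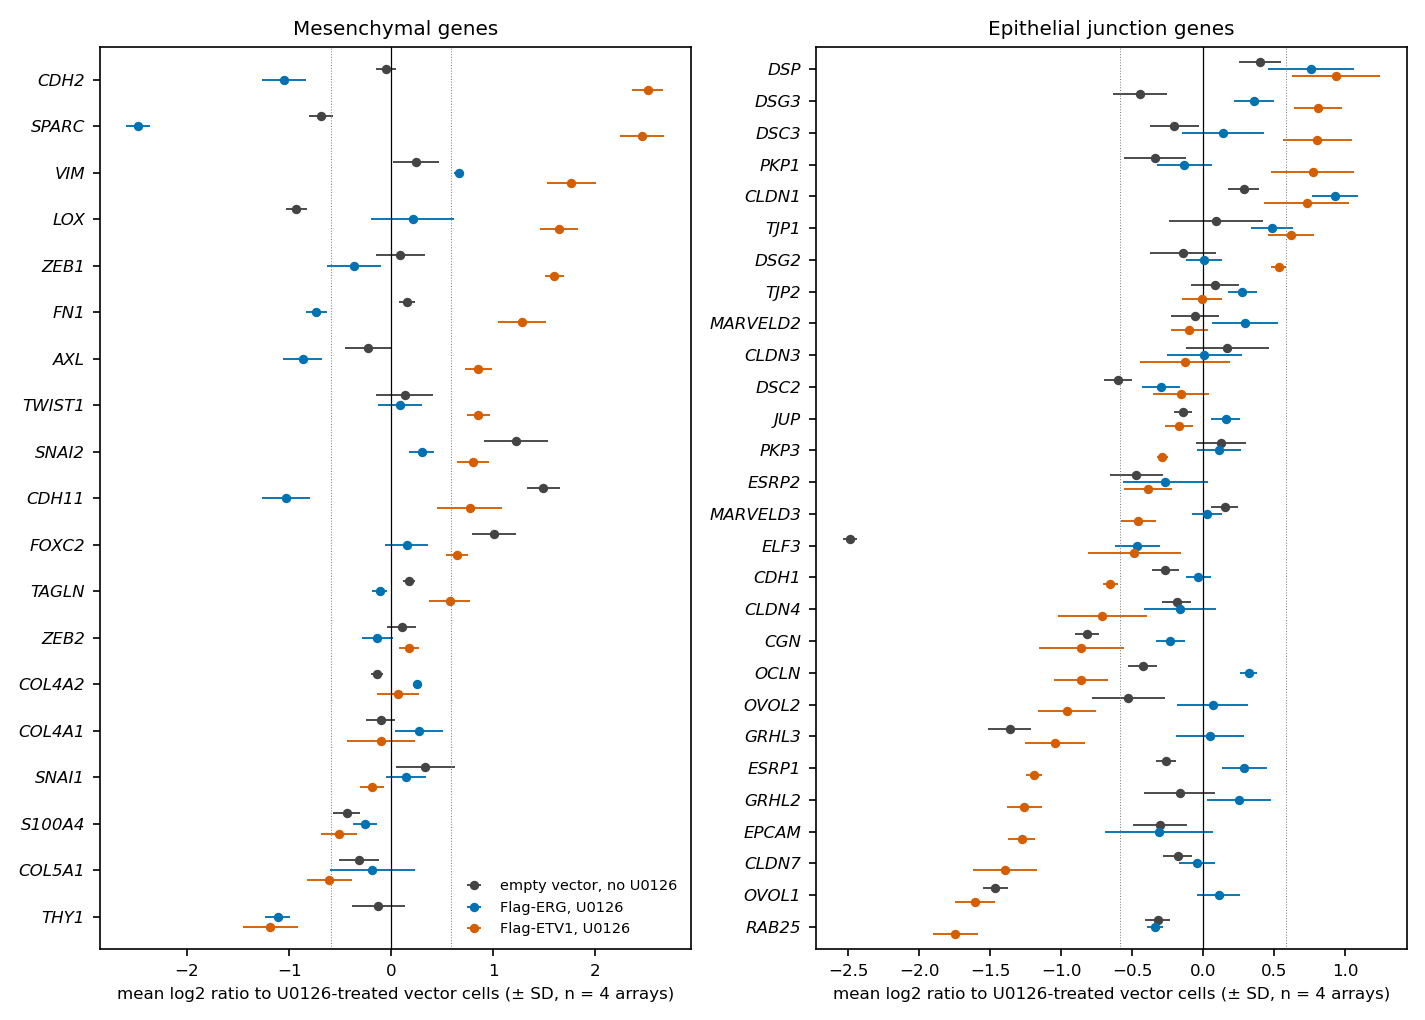
Mean log2 ratio to U0126-treated vector cells (x axis) of 19 mesenchymal genes (left) and 28 epithelial junction genes (right), with points for the 3 groups, bars of 1 SD over 4 arrays and dotted lines at 1.5-fold. With ETV1, 11 of the 19 were called higher and 12 of the 28 lower, against 1 and 0 with ERG.

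Markers of prostate basal cells rose in 6 of 14 genes and fell in 1 (adjusted p = 0.000209, and 0.0301 with an estimated correlation), with the keratins KRT6A at 0.90 ± 0.31 and KRT17 at 0.88 ± 0.14. Luminal markers fell in 5 of 18 genes and rose in none, with KRT8 at -0.90 ± 0.07 and KRT18 at -0.81 ± 0.12 (adjusted p = 0.0293, and adjusted p = 0.0661 with an estimated correlation). Of 26 keratinocyte differentiation genes, 10 fell, KLK10 (-2.19 ± 0.32) and SPRR3 (-2.16 ± 0.21) among them, and 2 rose, KRT10 (0.70 ± 0.28) and TGM1 (1.20 ± 0.23) (adjusted p = 0.000319, and adjusted p = 0.0661 with an estimated correlation).

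The list of MAPK feedback and ETS output held 6 genes that rose with ETV1 and 5 that fell, of 25 (adjusted p = 0.923), with a median of -0.18 and a mean of 0.04. Camera tests a net shift, so its p does not speak to change in both directions. Over all 17185 genes, 625 were higher and 975 lower with ETV1. Fry's mixed test of change in either direction gave adjusted p = 1.5e-12 for the list, but it does not compare the list with other genes. FOSL1 (1.46 ± 0.08), EPHA2 (1.16 ± 0.30), TNC (1.11 ± 0.14), DUSP4 (1.02 ± 0.32), DUSP5 (0.93 ± 0.21) and IL11 (0.61 ± 0.13) rose. ETV4 (-0.93 ± 0.18), HMGA1 (-0.67 ± 0.23), SLC4A7 (-0.66 ± 0.18), PHLDA2 (-0.65 ± 0.19) and SPRY4 (-0.61 ± 0.17) fell, and DUSP6 stood at -0.36 ± 0.17. Of 26 growth factors and cytokines, 7 rose and 2 fell (adjusted p = 0.00303, and 0.0301 with an estimated correlation). The inflammatory cytokines IL1A (2.00 ± 0.13) and IL1B (1.19 ± 0.09) rose, and HBEGF (-1.21 ± 0.20) and PDGFB (-1.05 ± 0.10) fell. Of 36 genes of proteolysis, adhesion and migration, 8 rose and 1 fell (adjusted p = 0.00972, and 0.0301 with an estimated correlation). The protease inhibitor SERPINB2 (1.55 ± 0.54) rose and the collagenase MMP1 (-1.37 ± 0.15) fell. Immediate early genes went both ways. JUN (0.88 ± 0.31) and MYC (0.83 ± 0.14) were among 5 of 25 that were higher, and 6 were lower, including IER2 (-1.26 ± 0.16), FOS (-1.23 ± 0.26), NR4A1 (-1.15 ± 0.09) and EGR1 (-1.04 ± 0.12) (adjusted p = 0.435).

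Cholesterol synthesis genes were lower with ETV1 in 4 of 21 cases and higher in none (adjusted p = 0.00303, and 0.0301 with an estimated correlation), with HMGCS1, an early enzyme of the pathway, at -1.06 ± 0.16 and SC5D at -0.87 ± 0.13. Interferon response genes rose in 9 of 22 cases, including IFI44L (1.05 ± 0.11) and IFI6 (0.96 ± 0.27), and USP18 (-1.53 ± 0.18), a protease that removes ISG15, fell (adjusted p = 7.65e-05, and adjusted p = 0.0832 with an estimated correlation). In the stress list 3 of 20 genes rose, XBP1 (0.81 ± 0.19), DDIT3 (0.69 ± 0.19) and SLC7A11 (0.67 ± 0.21) (adjusted p = 0.0275, and adjusted p = 0.0832 with an estimated correlation). FOXO and quiescence genes (2 of 24 rose, 4 fell, adjusted p = 0.353), ribosome and MYC genes (0 of 26 called, 0.429) and cell cycle genes (2 of 36 rose, 1 fell, 0.777) did not pass. Of the called members near 1.5-fold, PHLDA2 (-0.58) and IL11 (0.55) lost their call without ETV1 replicate 1, COL5A1 (-0.51) without replicate 3, and HMGA1 (-0.56), SPRY4 (-0.54) and TJP1 (0.55) without replicate 4.

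ERG and ETV1 cells were compared directly, since both were measured with the same dyes against the same kind of reference, so an equal dye effect cancels. The largest difference was in SPARC, at -2.48 ± 0.11 with ERG and 2.46 ± 0.22 with ETV1, a difference of -4.94 on the log2 scale (SE 0.13). CDH2 differed in the same sense, at -1.05 ± 0.21 with ERG and 2.51 ± 0.15 with ETV1, and SLC38A5 stood at -3.65 ± 0.21 and 1.19 ± 0.24. APOD stood at 1.63 ± 0.17 with ERG and -1.60 ± 0.12 with ETV1, and KLK6 at 0.19 ± 0.29 and -2.83 ± 0.17. In this contrast 911 genes were higher with ERG and 706 higher with ETV1, 1617 in all, and 304 and 272 of them differed by at least 2-fold.

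Several lists also differed between ERG and ETV1. None of 19 mesenchymal genes was higher with ERG and 10 were higher with ETV1 (adjusted p = 9.66e-10, and 0.00258 with an estimated correlation), fibronectin (FN1, difference -2.02) and ZEB1 (-1.96) among them. Of 28 epithelial junction genes, 11 were higher with ERG and 2 with ETV1 (adjusted p = 5.03e-06, and 0.00641 with an estimated correlation). OVOL1 differed by 1.71, the transcription factor GRHL2 by 1.51 and the splicing regulator ESRP1 by 1.48. Basal markers were higher with ETV1 in 6 of 14 genes and with ERG in 1 (adjusted p = 3.7e-05, and 0.0242 with an estimated correlation), the nerve growth factor receptor NGFR (-1.34) and DLK2 (-0.91) on the ETV1 side. Luminal markers were higher with ERG in 5 of 18 genes, DPP4 (1.35) and STEAP2 (1.03) among them, and with ETV1 in none (adjusted p = 0.0215, and adjusted p = 0.0583 with an estimated correlation). Growth factors and cytokines were higher with ETV1 in 10 of 26 genes and with ERG in 2 (adjusted p = 0.000242, and 0.00737 with an estimated correlation), with IL1A at -2.84, AREG at -2.37 and IL1B at -2.06. Cholesterol synthesis genes were higher with ERG in 7 of 21 cases and with ETV1 in none, HMGCS1 (1.33) and SC5D (0.70) among them (adjusted p = 1.37e-06, and 0.00258 with an estimated correlation). Of the other called members, IDI1 (0.62) lost its call without ETV1 replicate 1 (0.56) and INSIG1 (0.67) without ERG replicate 4 (0.58). Interferon response genes were higher with ERG in 9 of 22 cases and with ETV1 in 1 (adjusted p = 0.0142, and adjusted p = 0.372 with an estimated correlation), USP18 differing by 1.58 and BST2 by -2.88.

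The list of MAPK feedback and ETS output did not pass between ERG and ETV1. DUSP4 (-1.24), FOSL1 (-1.11), DUSP5 (-0.97), EPHA2 (-0.93) and IL11 (-0.73) were higher with ETV1 and SPRY4 (0.63) and SLC4A7 (0.86) with ERG, of 25 genes (adjusted p = 0.837, median 0.16, mean -0.03). SPRY4 lost its call without ERG replicate 1 (0.46) and without ETV1 replicate 4 (0.56). Immediate early genes (3 of 25 higher with ERG, 7 with ETV1, adjusted p = 0.365) and keratinocyte differentiation genes (7 of 26 and 2, 0.0655) did not pass. For proteolysis, adhesion and migration, 7 of 36 genes were higher with ERG and 8 with ETV1 (0.357, median 0.01, mean -0.10). FOXO and quiescence genes split 3 and 4 of 24 (0.837, median 0.05, mean -0.02). Stress genes (1 of 20 and 0, 0.837), ribosome and MYC genes (1 of 26 and 0, 0.713) and cell cycle genes (0 of 36 and 3, 0.261) did not pass.

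**Figure D3:**
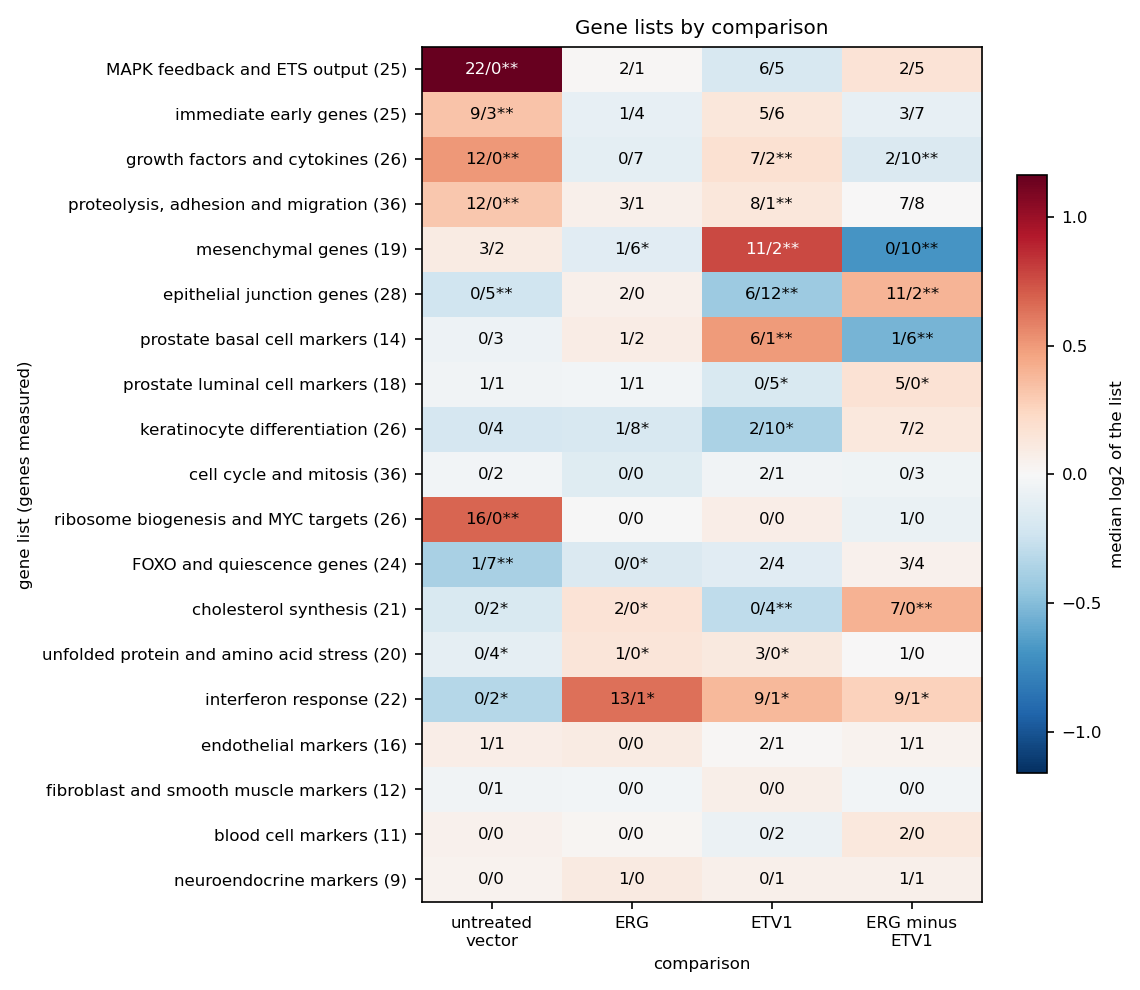
Median log2 ratio to U0126-treated vector cells (colour; for the last column the ERG minus ETV1 difference) of 19 gene lists (y axis, with the number of measured genes) in the 4 comparisons (x axis). Each cell gives genes called higher and lower, with 1 asterisk for an adjusted p under 0.05 in camera and a second where it holds with an estimated correlation; MAPK feedback genes show 22 and 0 without U0126.

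Marker lists of other cell types passed in no comparison. Endothelial markers had 1 gene higher and 1 lower of 16 without U0126 (adjusted p = 0.314) and 0 of 15 called with ERG (0.276). With ETV1, 2 of 16 were higher and 1 lower (0.353), and between ERG and ETV1 1 of 15 was higher and 1 lower (0.965). Fibroblast and smooth muscle markers had 1 of 12 lower without U0126, COL1A1 (-0.65 ± 0.26, adjusted p of the list 0.738), and no call elsewhere (0.826, 0.864 and 0.837). COL1A1 lost its call without untreated replicate 4 (-0.53). Blood cell markers had 0 of 11 called without U0126 (0.675) and with ERG (0.822), 2 lower with ETV1 (0.286) and 2 higher with ERG than with ETV1 (0.192). Neuroendocrine markers had 0 of 9 called without U0126 (0.547), 1 higher with ERG (0.177), 1 lower with ETV1 (0.415) and 1 on each side between them (0.837). The secretory granule protein CHGB stood at 0.79 ± 0.24 with ERG and -0.78 ± 0.26 with ETV1.

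The genes that changed with an ETS protein under U0126 were set against those that differ without U0126, since the series asks whether the ETS proteins act on the same program. The integrins ITGA2 (2.67 ± 0.37 without U0126, 1.10 ± 0.25 with ERG) and ITGB6 (1.45 ± 0.31 and 1.25 ± 0.29) and the activin antagonist follistatin, FST (2.84 ± 0.18 and 1.07 ± 0.28), were higher in both the untreated and the ERG comparison. RRAD, a GTPase of the RGK family (-1.86 ± 0.03 and -1.95 ± 0.16), and the p53 relative TP73 (-1.84 ± 0.26 and -1.69 ± 0.21) were lower in both. Between the untreated and the ETV1 comparison, the matricellular protein THBS1 (1.93 ± 0.23 without U0126, 1.78 ± 0.14 with ETV1), FOSL1 and IL1A were higher in both. BMF and OVOL1 were lower in both.

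Of the 670 genes higher without U0126, 77 (11.5%) were higher with ERG and 23 (3.4%) lower, against 1.4% and 1.9% of the genes without a call in the untreated comparison. With ETV1, 101 (15.1%) were higher and 47 (7.0%) lower, against 3.1% and 4.5%. Of the 748 genes lower without U0126, 116 (15.5%) were lower with ERG and 15 (2.0%) higher, and 212 (28.3%) were lower with ETV1 and 38 (5.1%) higher. Among those lower without U0126 by at least 2-fold, 63 were also lower with ETV1 and the remaining 63 were not. In the whole of this set 8 (6.3%) were higher with ETV1, and 31 (24.6%) were lower and 6 (4.8%) higher with ERG. Among the 184 that were higher by at least 2-fold, 38 (20.7%) were higher and 23 (12.5%) lower with ETV1, and 20 (10.9%) were higher and 12 (6.5%) lower with ERG. Named examples of opposite movement included HBEGF (1.29 ± 0.30 without U0126, -1.21 ± 0.20 with ETV1), SPRY4 (3.85 ± 0.17 and -0.61 ± 0.17) and FOS (1.29 ± 0.22 without U0126, -0.75 ± 0.33 with ERG).

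**Figure D4:**
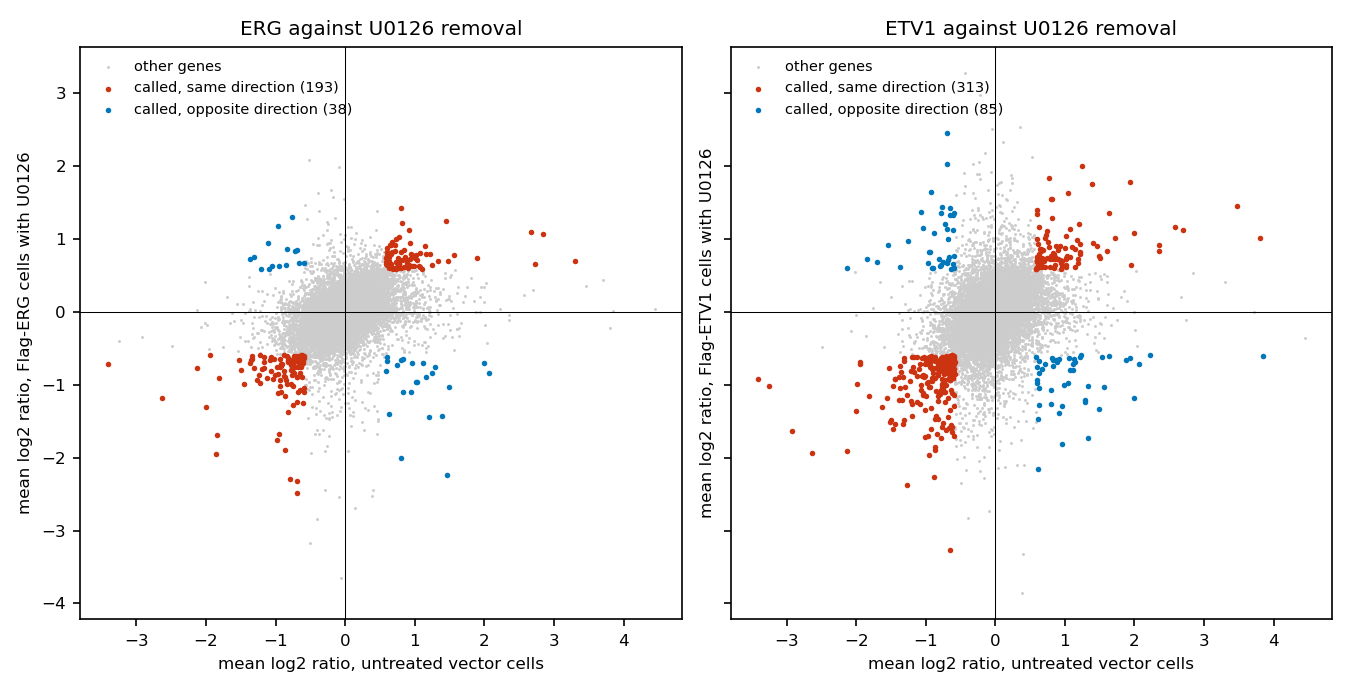
Mean log2 ratio to U0126-treated vector cells of 17185 genes in vector cells without U0126 (x axis) against Flag-ERG cells (left, y axis) and Flag-ETV1 cells (right, y axis) with U0126. Genes called in both comparisons are coloured: 193 in the same direction and 38 in opposite directions for ERG, 313 and 85 for ETV1.

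Independent lists of these lengths would share 12.1 higher and 18.8 lower genes between the untreated and ERG comparisons, where 77 and 116 were shared. Between the untreated and ETV1 comparisons they would share 24.4 and 42.4, where 101 and 212 were shared. In opposite directions they would share 16.8 and 13.5 with ERG, where 23 and 15 were found, and 38 and 27.2 with ETV1, where 47 and 38 were found (higher without U0126 first). All comparisons share the kind of reference RNA, so a simulation of unchanged groups against a shared reference was run with 100 draws, and it gave 0 shared calls in every draw. Unchanged groups give almost no calls by construction, so this count alone decides nothing about a shared term. The simulated reference noise was shared only by arrays of the same replicate number, so a term common to all arrays was left out. Across genes, which are not independent replicates, log2 ratios of the untreated and ERG comparisons correlated with r = 0.367 (simulated mean 0.148) and a covariance of 0.0386 (simulated 0.00167). For untreated and ETV1 the r was 0.308 (0.145) and the covariance 0.042 (0.00164). Among the 14268 genes called in no comparison, r was 0.437 for untreated with ERG, 0.346 for untreated with ETV1 and 0.382 for ERG with ETV1, above the simulated values, so the simulation left out part of what the comparisons share. Set from arrays with different replicate numbers, 2 per group, the shared calls numbered 188 to 227 for ERG and 325 to 357 for ETV1. Part of the overlap may still come from the reference or from dye effects, which no split of these arrays removes.

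ERG and ETV1 shared 80 higher genes (11.3 for independent lists) and 140 lower genes (24.5), and 35 (17.6) were higher with ERG and lower with ETV1 and 69 (15.7) the reverse, so opposite calls also exceeded the number for independent lists. Lower in both were the calcium-binding protein calretinin, CALB2 (-2.54 ± 0.25 with ERG, -2.73 ± 0.21 with ETV1), GSDMC (-2.52 ± 0.12 and -3.86 ± 0.17), STEAP1 (-2.45 ± 0.07 and -3.33 ± 0.07) and the embryonic globin HBE1 (-2.69 ± 0.07 and -2.13 ± 0.34). Higher in both were the keratin KRT75 (1.03 ± 0.38 and 1.84 ± 0.26), the stress-responsive NDRG1 (1.09 ± 0.15 and 0.99 ± 0.11) and IFI6. The correlation across genes was 0.273 (simulated mean 0.147), the covariance 0.03 (simulated 0.00165), and arrays of different replicate numbers shared 207 to 257 calls. In all 3 comparisons 32 genes were higher (0.4 for independent lists) and 43 lower (1.1).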

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

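The test of genes called in all 3 comparisons and the count of lists under other splits were set before their results were seen; the tests of genes called in 2 comparisons, of chance values of the reference, of the shared falls, of the interferon genes and of gene counts under other splits were chosen after. For 6 of 201 gene and group values, 1 array lay far from the other 3, where chance gives about 1 in 20. CYP1A1 read -3.74 on untreated replicate 1 (others -3.31 to -3.28) and RRS1 1.11 on untreated replicate 2 (others 1.39 to 1.44). On ERG replicate 4, ETV1 read 0.31 (others 0.03 to 0.07) and OASL 2.04 (others 1.22 to 1.32). KLK6 read -2.57 on ETV1 replicate 1 (others -2.96 to -2.89) and KRT18 -0.63 on ETV1 replicate 4 (others -0.88 to -0.85). Accessions without a name, left out of the comparisons, held many calls in limma: 1808 without U0126 (1008 higher, 800 lower), 1019 with ERG (576 and 443), 1987 with ETV1 (993 and 994) and 1902 between ERG and ETV1 (1015 and 887). An unnamed accession stood at 6.35 ± 0.19 with ERG, against 0.36 without U0126 and 0.07 with ETV1. Another stood at 5.48 ± 0.39 with ETV1, against 0.86 without U0126 and -0.09 with ERG, and one more at 5.07 ± 0.34, against 0.70 and -0.14.

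Many genes were called in the same direction in several comparisons. There were 501 genes called in 1 direction in 2 comparisons and not in that direction in the third. Of these, 255 (50.9%) had a called difference from the third group in both. But they were chosen for lacking that call, and some were called the opposite way in the third comparison. An equal dye or reference term with an opposite change in the third group would give the same values. Such a term therefore cannot be told apart. Chance values of a shared reference gave at most 0 shared calls in 100 simulated draws, which decides nothing, because unchanged groups give almost no calls by construction. Of 75 genes called in all 3 comparisons, 17 (22.7%) differed between some groups, 2 of 32 higher and 15 of 43 lower, which lies between the bounds set, so for this set an equal dye or reference term cannot be told apart from a change shared by the groups. Among 14268 genes called in no comparison, log2 ratios still correlated across genes at 0.437, 0.346 and 0.382 for untreated with ERG, untreated with ETV1 and ERG with ETV1.

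There were 97 genes, CALB2, STEAP1, GSDMC and HBE1 among them, that were lower with both ERG and ETV1 and not lower without U0126. Their median on the untreated arrays was -0.16, against -0.84 with ERG and -0.99 with ETV1, and 56 of the 97 were called lower than on the untreated arrays in both. The genes were chosen for not being called lower there, and 6 of them were called higher. These values therefore do not tell a dye effect equal on all arrays apart from a fall with both ETS proteins. Of the 97, 24 (24.7%) differed between ERG and ETV1, which lies between the bounds set. An expression state of the vector cells that supply every reference, for example in the population that was transduced with the empty vector, cannot be told apart from a fall common to both ETS proteins, which stays a hypothesis, because no second vector population was compared.

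The rise of 13 interferon response genes with ERG was weighed against 3 explanations. A dye effect equal on all arrays stays open for the rise over the reference. Of the 13, which were not chosen by their untreated values, 12 were called higher on the ERG than on the untreated arrays. On the untreated arrays 0 of the 13 were called higher. These groups also differ in U0126, however. A dye effect offset by lower RNA without U0126 (list median -0.328 on the untreated arrays) would give the same values. Between ERG and ETV1, both with U0126, an equal dye effect cancels. It therefore cannot be the source of the difference in the 8 of the 13 that were larger with ERG than with ETV1. A response in 1 of the 4 ERG samples is argued against by 11 of the 13 being called in every fit that leaves out 1 ERG array. A state of the transduced population that does not depend on the ETS protein stays open: with ETV1, 9 list members rose, 8 of them among the 13, while 8 of the 13 were larger with ERG, and the interferon list passed neither comparison with an estimated correlation (adjusted p = 0.0741 and 0.0832). A response to ERG itself cannot be told apart from it, because each construct is represented by 1 cell population as far as the labels say.

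Other splits of the arrays were counted for each comparison. Against the reference the 4 arrays of a group allow 8 sign patterns, too few for a share under 0.05; 1 of 8 patterns, the real one, gave as many genes in each comparison, 1418, 741 and 1600, and the highest other gave 0. Of the 35 splits of the 8 ERG and ETV1 arrays, 1, the real one, gave as many genes (1618 in a fit of these arrays), and the highest other gave 0. If all 8 arrays are exchangeable, this excludes chance in the spread between arrays for that count. It does not cover a chance difference between the cell populations, since each construct is represented by 1 population as far as the labels say. The replicate numbers may also pair the arrays, and only 8 of the 35 splits part every pair, too few for a share under 0.05. Of these 8, the real one gave 1618 genes and the highest other gave 0. As many lists, 7, passed in 2 of the 35 splits, so chance cannot be excluded for the number of lists by this count. The other split set ERG replicates 1, 2 and 3 with ETV1 replicate 4 against the rest; it parts as many same-numbered pairs as the real one and keeps part of the real difference.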

How the results depend on the processing

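All accessions tested together, and the replicate block joined with no minimum change, were chosen after the data were seen; the other alternatives were planned. Counts of called genes are given in the order untreated, ERG, ETV1, ERG against ETV1, then genes shared by untreated and ERG, untreated and ETV1, and ERG and ETV1. The stated counts were 1418, 741, 1600, 1617, 193, 313 and 220. Under 12 alternatives each count stayed within 1.5-fold; they included 3 normalizations, other probe summaries, robust or separate fits, replicate blocks, all accessions and adjusted p under 0.01. Their ranges were 1324 to 1534, 659 to 892, 1483 to 1691, 1435 to 1681, 149 to 232, 284 to 351 and 185 to 259. Of genes changed by at least 1.5-fold, 0 missed the adjusted p in the untreated, ERG and ETV1 comparisons, and 2 between ERG and ETV1. The minimum change therefore set nearly all calls. Robust or separate fits, replicate blocks and the stricter adjusted p keep the group means, so their near-identical counts test little. A group's mean also stays the same when an array of another group is left out. Leaving out each array in turn gave 1418 to 1506, 741 to 805, 1600 to 1730, 1617 to 1706, 188 to 202, 302 to 330 and 210 to 232, and 33 to 34 of the 76 list tests. With genes of above-median spread between replicates left out, which tests fewer genes, the counts were 740, 372, 813, 826, 94, 161 and 100. With no minimum change they were 6358, 4625, 6291, 3089, 2249, 2544 and 2056, and at 2-fold or more 310, 146, 441, 576, 7, 45 and 31, as the thresholds' own construction gives.

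With the replicate block the counts were 1418, 741, 1600, 1619, 193, 313 and 220, and with the block and no minimum change together they were 7003, 5305, 6879, 3632, 2663, 2921 and 2432. The block ended the call of the cholesterol list without U0126 (adjusted p = 0.0504), so that 32 list tests passed, and changed no other call of a list or named gene. Untreated arrays were not taken as paired by number with the others, since not every same-number correlation was over 0.1: the correlations across genes were 0.242, 0.008, 0.009 and 0.23 with ERG and 0.183, 0.047, -0.02 and 0.085 with ETV1, while 6 of 12 arrays correlated best with their own number in both other groups, a hint of pairing from the data.

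Of the 76 list tests 33 passed, 18 with an estimated correlation, 57 with fry's directional test and 75 with its mixed test; fry does not compare a list with other genes, and the cause of the differences was not tested further. No list or named gene turned its direction beyond its threshold under any alternative run. Of 3605 values of named genes under alternatives, 3551 kept their side of the threshold. In 25 results 53 values lost the call, and 1, EPHA4 without untreated replicate 1 (-0.65), gained it. Apart from left-out arrays, calls were lost with the mean over probes (DSC2, ETV4, FSCN1, XBP1, COL5A1, HMGA1, KRT10, PHLDA2, SLC4A7, IDI1, INSIG1), with single probes (ETV4, MVK, MMP2, TNC, PHLDA2, TJP1, IDI1, SPRY4) and with scaling or quantile normalization (MVK, COL5A1, KLK11). Keratinocyte differentiation passed in vector cells without untreated replicate 3 (adjusted p = 0.0481). Between ERG and ETV1 the same list passed without single arrays (0.0276 without ERG replicate 3, 0.0424 without ERG replicate 4 and 0.036 without ETV1 replicate 4). Growth factors passed with ERG without ERG replicate 4 (0.0357). Signal over background is unknown for these arrays, so it is not known which genes are too dim to show a change.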

Other observations

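The families in this part were chosen after the results were seen, and their members were counted with the same threshold as above; the test on the aryl hydrocarbon receptor was set before its result was seen. Of 25 measured ETS transcription factors, 8 were higher without U0126 and 2 lower. Beside ETV5 and ETV4, the higher ones were FLI1 (1.43 ± 0.30), ETS1 (1.15 ± 0.38), SPDEF (1.13 ± 0.13), ELK3 (0.92 ± 0.13), FEV (0.81 ± 0.18) and ETV6 (0.75 ± 0.29), and the lower ones ELF3 (-2.49 ± 0.05) and ETS2 (-1.06 ± 0.11). With ERG 1 member was higher and 1 lower, with ETV1 2 and 1, and between ERG and ETV1 2 and 1. The 1 higher with ERG was FEV (1.43 ± 0.36), a close relative of ERG, which stood at 0.77 ± 0.08 with ETV1; probe sequences were not used, so signal from the construct in its probes was not tested.

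Among 13 measured AP-1 genes, 5 were higher without U0126 (FOSL1, MAFF, FOS, MAFK and FOSB) and 1, ATF3, lower, with MAFF at 1.81 ± 0.28 and FOSB at 0.70 ± 0.14. With ETV1, FOSL1, JUND (1.26 ± 0.18) and JUN (0.88 ± 0.31) were higher and FOS lower, and with ERG, ATF3 was higher and FOS lower. Between ERG and ETV1, 0 were higher with ERG and 3 with ETV1. Of 15 secreted kallikrein proteases, 8 were not called with ETV1, 0 were higher and 7 were lower, KLK5 (-3.27 ± 0.15), KLK6 (-2.83 ± 0.17), KLK7 (-1.96 ± 0.25), KLK8 (-0.92 ± 0.13), KLK9 (-1.76 ± 0.13), KLK10 (-2.19 ± 0.32) and KLK11 (-0.59 ± 0.06). With ERG 2 were lower, KLK5 (-0.68 ± 0.20) and KLK9 (-1.03 ± 0.27), 2 were lower without U0126, and 5 were higher with ERG than with ETV1. None of the printed values of these families changed sign under any scaling alternative run, but KLK11 lost its call when arrays were scaled to one median absolute deviation (-0.58) or quantile normalized (-0.56), and without ETV1 replicate 2 (-0.58) or 4 (-0.57).

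The lower CYP1A1 (-3.41 ± 0.22) and CYP1B1 (-3.25 ± 0.10) without U0126 raised the hypothesis that U0126 raises targets of the aryl hydrocarbon receptor. Of 4 other measured targets, 2 were called lower without U0126, TIPARP (-0.81 ± 0.08) and ALDH3A1 (-1.31 ± 0.25). CYP1A2 (-0.47 ± 0.14) and NQO1 (-0.36 ± 0.22) were not called. Both were lower in limma (adjusted p = 0.000328 and 0.0142) but changed by less than 1.5-fold. At least 3 would have borne the hypothesis out and at most 1 would have argued against it, so it stays open.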
